A study of Rattus norvegicus with 15 samples.

How the data were processed

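RNA from 15 mammary tumours of female Sprague-Dawley rats was measured on 15 single-colour (Cy3) Agilent rat expression arrays, 5 for each of 3 early-life zinc diets. Per the labels' protocols, 16 dams per group received chow with 35 (adequate), 3 (deficient) or 180 (supplemented) mg of zinc per kg from gestation day 10 until weaning on day 21, their daughters stayed on the same chow until day 51, and each daughter then received 50 mg/kg of 7,12-dimethylbenz[a]anthracene (DMBA), a carcinogen that causes mammary tumours in rats, by gavage. All animals ate adequate chow after that, per the labels' protocols, and the tumours were taken at 180 days. The group that the labels call the negative control was read as the adequate diet, because the other groups carry the names of the other chows. One free-text label field describes mammary gland at day 21 instead; the characteristics and the design text, which give tumours at 180 days, were followed.

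The scanner files hold spot intensity on a linear scale, which was background-subtracted and detrended by Agilent Feature Extraction 11.5.1.1, per the file headers. The submitters' processing notes give version 15.5 instead. A second table that the authors deposited holds log2 values for 30002 of the 41012 probes on the array. Its steps are not given in the sources used here. Its array medians lay between 7.09 and 7.10, and its columns tracked the log2 median spot signal before background subtraction with Pearson correlations across probes of 0.984 to 1.000, so the scale was read as log2 without centring by gene; the exact normalization stays unknown. It served as an alternative.

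Levels were log2 processed signals minus the 75th percentile of their own array over non-control probes. Spots with a non-uniformity or population outlier mark were set to missing, and spots of a probe were averaged, 263 probes having 10 spots each. Probes well above background on at least 5 of the 15 arrays were kept, which left 21011 probes with 40 missing values. Genes were named from the probe's accession, without its version, through a RefSeq table of assembly GRCr8; 17502 probes (42.7%) matched a single gene each, 0 matched several, and the rest stayed unnamed here. Of the tested probes 10710 had a symbol, for 8378 genes. The array was designed on another genome build, so no coordinates are given. A gene with several tested probes is shown by the probe with the highest mean level, and named genes whose probes disagree in sign are pointed out.

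The 3 diets were compared in 1 linear model per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom, two-sided, Benjamini-Hochberg adjustment over the tested probes, threshold 0.05, no fold minimum), as pairwise differences, as an F test over the 3 diets and as a slope over log2 dietary zinc. Of 30 gene lists fixed beforehand, 29 had at least 5 measured members and were tested with limma's camera, with the correlation between genes estimated for each list; the list of B cells and plasma cells had 2 measured members and was not tested. Camera with a preset correlation of 0.01 and fry were alternatives. Fry tests whether the genes of a list move on balance in one direction and does not compare the list with other genes. The mean level of each list was also compared by an exact permutation test over all splits of the 10 tumours. Genes were named by a rule: the 8 genes with the smallest p higher and lower against control and the 5 higher and lower between supplemented and deficient (leaving out symbols that are only clone, locus or predicted-gene numbers), 4 members of each list called by camera with estimated correlations (0 were), zinc transporter and metallothionein genes with an unadjusted p under 0.05, and Mt1, Mt2A, Slc30a1, Esr1, Pgr, Erbb2 and Mki67. Designs, lists, this rule and the alternatives below were set before the data were examined. Chosen after the values were seen were the exact permutation test of list levels, the leaving out of symbols of the chromosome-and-frame form, the work on array brightness, and 2 alternatives (brightness as a covariate, and leaving out the 3 dimmest arrays). Other list members and highly variable genes that are named were also chosen after their values were seen.

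The arrays lay on 4 slides, each with all 3 diets, and were scanned on 2 days. They differed in brightness: between 13854 and 24009 of the 43379 non-control spots stood well above background, the 75th percentile of the processed signal ran from 50.7 to 177, and 0 spots were saturated. The number of arrays limits the precision. The median half-width of the 95% interval of a log2 difference between diets was 0.51, a factor of 1.43. On data simulated for the comparison of deficient with control (20 data sets, 200 of 20971 probes changed on top of the shuffled residuals of the real arrays), limma recovered 40.0% of 2-fold and 88.0% of 4-fold changes at adjusted p 0.05, with 3.85 false calls per data set. In the same kind of data without changes, on 8369 genes for that comparison, camera with a preset correlation called on average 7 of 29 lists and camera with estimated correlations called 0. Alternatives covered the replicate number or the slide as a block, normexp background correction with quantile normalization, quantile, median and cyclic loess normalization, the filter, outlier spots, the deposited value table, the samples in the fit, the variance model, array weights, the probe of a gene, thresholds, covariates for tissue composition and leaving out each array. Normexp used median spot and background signals (offset 50), since mean spot signals were not used here. The covariate for B cells rested on the 2 measured members.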

Results

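The series asked how zinc in the diet of the mother and the young animal bears on gene expression in mammary tumours that arise in adulthood after DMBA. It holds 5 tumours from rats raised on zinc-deficient chow (3 mg/kg), 5 from rats raised on adequate chow (35 mg/kg, the control) and 5 from rats raised on supplemented chow (180 mg/kg). Levels are log2 signals relative to the 75th percentile of the array. The labels do not say whether the 5 tumours of a diet came from separate animals or litters, so the p-values measure the spread between these tumours.

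Diet did not separate the tumours detectably over all probes. The mean correlation between arrays of a diet was 0.951, the same as between arrays of different diets, and the difference of -0.000604 lay within chance (two-sided permutation test, 100000 resamples, p = 0.695); for arrays of the same slide the difference was 0.00219 (permutation p = 0.262). No probe passed the moderated F test over the 3 diets (0 of 21011 in limma, lowest adjusted p = 0.990, 847 probes at an unadjusted p under 0.05), and 0 followed dietary zinc (lowest adjusted p = 0.419, 1617 at an unadjusted p under 0.05, where 1051 are due by chance). That unadjusted count was not compared with regrouped tumours, and probes are not independent, so the excess alone shows no trend. Genes of milk secretion were among those that varied most between single tumours: the milk protein gene Csn1s1, well above background on 15 of 15 arrays, spanned 5.64 log2 units. Glycam1 and Csn1s2a reached 6.16 and 2.95 and were well above background on 12 and 7 arrays, so their lowest levels were at background.

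Tumours from deficient rats were set against controls to ask what early zinc deficiency leaves behind. Penk, which encodes the opioid peptide precursor proenkephalin, had a level of 2.75 ± 0.98 (SD, n = 5) in deficient tumours and 4.64 ± 0.62 (n = 5) in controls, a log2 difference of -1.89 with a 95% interval from -2.92 to -0.86. It differed by -2.70 to -1.74 within the 4 slides and by -1.89 with slide as a block. The brain-type creatine kinase Ckb stood at 2.62 ± 0.36 against 3.47 ± 0.33, a log2 difference of -0.85. Red cell genes were on the other side: Ahsp, the chaperone of alpha globin, differed by 1.26, from -2.45 ± 0.51 in controls to -1.19 ± 0.71 in deficient tumours, and was well above background in 4 deficient and 2 control tumours. With normexp and with the deposited values it differed by 0.30 and 0.32, and Ckb by -0.52 and -0.55. None of these passed the test: limma called 0 of 21011 probes between the diets (lowest adjusted p = 0.444). At an unadjusted p under 0.05 there were 822 probes, where 1051 are due by chance. Every gene named for this comparison had an adjusted p of 0.987.

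Among the remaining genes with the smallest p that were lower in deficient tumours, the log2 differences were -0.99 for Ift22, a protein of intraflagellar transport, -0.90 for Nipa2, a magnesium transporter, -0.83 for Pld3, -0.78 for Gpr137, -0.70 for F11r, the junctional adhesion molecule A, and -0.48 for Akr7a2. Among those higher, they were 1.88 for the olfactory receptor Or5b123b, 1.15 for Tmcc3, 0.80 for Tgfb2, which encodes transforming growth factor beta 2, 0.77 for Ppp1r9a, 0.71 for Rufy3, 0.68 for Wipi1, which takes part in autophagy, and 0.67 for the splicing kinase Clk4. Several of these genes were near background. Or5b123b was well above it in 4 deficient tumours and 1 control tumour, Ift22, Nipa2 and Gpr137 in 2 deficient and 4 control tumours each, Tgfb2 in 4 deficient and 3 control tumours, Tmcc3 and Wipi1 in 4 of each, and Ppp1r9a in 5 deficient and 4 control tumours. Without the 3 dimmest arrays, the difference of F11r was -0.37.

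By list, erythrocyte genes had the highest median. All 5 measured members (Ahsp, Alas2, Hbb, Hbb-b1 and Hbe2) were higher in deficient tumours than in controls, with a median log2 difference of 1.26 and differences of the list mean from 0.24 to 2.81 within the 4 slides; 3 passed when adjusted over the list alone and 0 over all probes. Adjusting over 1 list alone does not account for the number of lists examined. The median was 0.49 with normexp and 0.53 with the deposited values. The bright Hbb-b1 moved less, from 1.4 to 1.27 with normexp. Hbe2 was well above background in 2 tumours of each of these diets. Milk protein and secretory genes were higher for 14 of 15 members, with a median of 0.77, which was 0.44 without control replicate 3, 1.24 without control replicate 4 and 0.42 with normexp. Among them were Btn1a1 at 1.25 and the transcription factor Elf5 at 1.14, well above background in 4 deficient tumours each and in 2 and 3 controls. Of the p53 target and apoptosis genes 18 of 23 were lower, with a median of -0.19, or -0.12 without control replicate 5; the cell cycle inhibitor Cdkn1a differed by -0.61, the survival factor Bcl2l1 by -0.49, the death promoter Bad by -0.41 and Phlda3 by -0.70. In the list of mast cells and eosinophils, 7 of 10 members were lower, with a median of -1.07 that rested on 1 tumour: it was -0.24 without deficient replicate 3. The member with the smallest p, Kit, was higher, by 1.03, and was well above background in 4 deficient tumours and 1 control tumour. With estimated correlations camera called 0 of 29 lists (1 at an unadjusted p under 0.05) and fry called 0; the adjusted p was 0.462 for erythrocytes, 0.532 for milk proteins, 0.532 for p53 targets and 0.884 for mast cells, and the other lists had adjusted p from 0.884 to 0.988. A preset correlation called 3 lists, erythrocytes (adjusted p = 5.59e-06), milk proteins (2.61e-05) and p53 targets (0.0167), and none of these calls held with an estimated correlation.

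Tumours from supplemented rats were set against controls to ask the same of extra zinc. Fmod, which encodes the collagen-binding proteoglycan fibromodulin, had a level of 3.55 ± 0.43 in supplemented tumours and 4.81 ± 0.47 in controls (SD, n = 5 each), a log2 difference of -1.26 with a 95% interval from -2.03 to -0.50. The chemokine gene Cxcl1 stood at 2.30 ± 0.37 against 0.94 ± 0.84, and the stromelysin gene Mmp3 at 2.60 ± 1.42 against 0.82 ± 0.83, log2 differences of 1.36 and 1.79. Cxcl1 was also higher in deficient tumours than in controls in each of the 4 slides, by 0.25 to 2.79. Between supplemented and deficient tumours Cxcl1 differed by -0.15 to 0.82 within the slides. The chaperone genes Dnaja1 and Chordc1 differed by 0.61 and 0.64 between supplemented tumours and controls. None passed: limma called 0 of 21011 probes, 415 had an unadjusted p under 0.05 where 1051 are due by chance, and the adjusted p of every gene named for this comparison was 1.000.

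The other genes higher in supplemented tumours by the smallest p were Nptx1 (1.09, a neuronal pentraxin), Otud7b (0.83, a deubiquitinase, with a second tested probe that differed in sign), Clk4 (0.75) and Pknox1 (0.58). Those lower were Car15 (-2.84, a carbonic anhydrase), Fam83d, Phykpl (-1.25), Guca2a (-1.08, the guanylin precursor), Pou6f1 (-0.90), Klhdc9 (-0.71) and H1f0 (-0.50, a linker histone). Fam83d was not well above background in any supplemented tumour; it was at least 1.05-fold higher in controls (adjusted p = 1.000). Such bounds set the mean of the brighter diet against, per array of the dimmer diet, the higher of the lowest signal well above background and the gene's own signal. Car15 was well above background in 5 control tumours and 1 supplemented tumour, Pou6f1 in 5 and 2, Guca2a in 4 and 1, and Phykpl in 3 and 1. Nptx1 and Pknox1 were so in 3 control and 5 supplemented tumours each. The difference of Phykpl was -0.15 with normexp. That of Car15 was -1.07 with normexp and -1.15 with the deposited values.

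Among the lists, 21 of 23 heat shock and unfolded protein response genes were higher in supplemented tumours than in controls, with a median log2 difference of 0.26, or 0.13 without control replicate 2 (adjusted p = 0.745 with an estimated correlation and all arrays). Of the cell cycle genes 29 of 30 were lower, with a median of -0.51, Ccnb1 among them at -1.03 and Kif20a at -0.88 (adjusted p = 0.745 with an estimated correlation). That median varied in size with the arrays and the processing: it was -0.28 without control replicate 3, -0.17 with normexp, -0.19 with the deposited values and -0.79 with array weights. Basal and myoepithelial genes had a median of -0.26, milk proteins 0.50 and erythrocyte genes -0.69, with adjusted p of 0.847, 0.916 and 0.745, and the other lists had adjusted p from 0.745 to 0.965. The basal median was -0.15 without control replicate 4, the milk median 0.03 without control replicate 3 and 0.79 without supplemented replicate 5, and the erythrocyte median -0.45 and -1.06 without control replicates 5 and 3. Camera with estimated correlations called 0 of 29 lists (1 at an unadjusted p under 0.05), and fry called 0. A preset correlation called these 5 lists, with adjusted p of 9.65e-07 for heat shock, 1.78e-08 for cell cycle, 0.0157 for basal genes, 0.0279 for milk proteins and 0.0134 for erythrocytes.

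The widest contrast in zinc was between supplemented and deficient tumours. All 5 measured erythrocyte genes were lower in supplemented tumours: Hbb-b1, a beta globin, stood at 4.31 ± 0.48 against 6.40 ± 1.02 in deficient tumours (SD, n = 5 each), a log2 difference of -2.09, and Hbb differed by -1.94. Alas2, the first enzyme of haem synthesis in red cells, was well above background in 4 deficient tumours and in 0 supplemented ones, and was at least 2.81-fold higher in deficient tumours (adjusted p = 0.615). The mean of the list was higher in each of the 5 deficient tumours, the lowest at 0.31, than in each of the 5 supplemented ones, the highest at -0.60. The difference of -1.80 has an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 can give, and an adjusted p of 0.230 over 29 lists. Since that p is the smallest possible, 1 list standing out alone could not pass this adjusted test. The list had a median of -1.94, or -1.59 with Alas2 at its bound, and its mean differed by -3.01 to -1.21 within the 4 slides; with slide as a block the median was -2.10. It was smaller in size with normexp (-0.78), with the deposited values (-0.82) and without the filter on dim probes (-0.68). The median without the filter also covers genes of the list that were well above background on fewer than 5 arrays. With normexp the bright Hbb-b1 still differed by -1.91, while the dim Ahsp differed by -0.355. In the fit reported above, all 5 genes passed when adjusted over the list alone and 0 over all probes. Adjusting over the list alone does not account for this list standing out among 29. Hbe2 was well above background in 2 deficient tumours and 1 supplemented tumour. Camera gave the list an adjusted p of 0.122 with an estimated correlation, fry 0.0398 and camera with a preset correlation 1.86e-09.

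**Figure D1:**
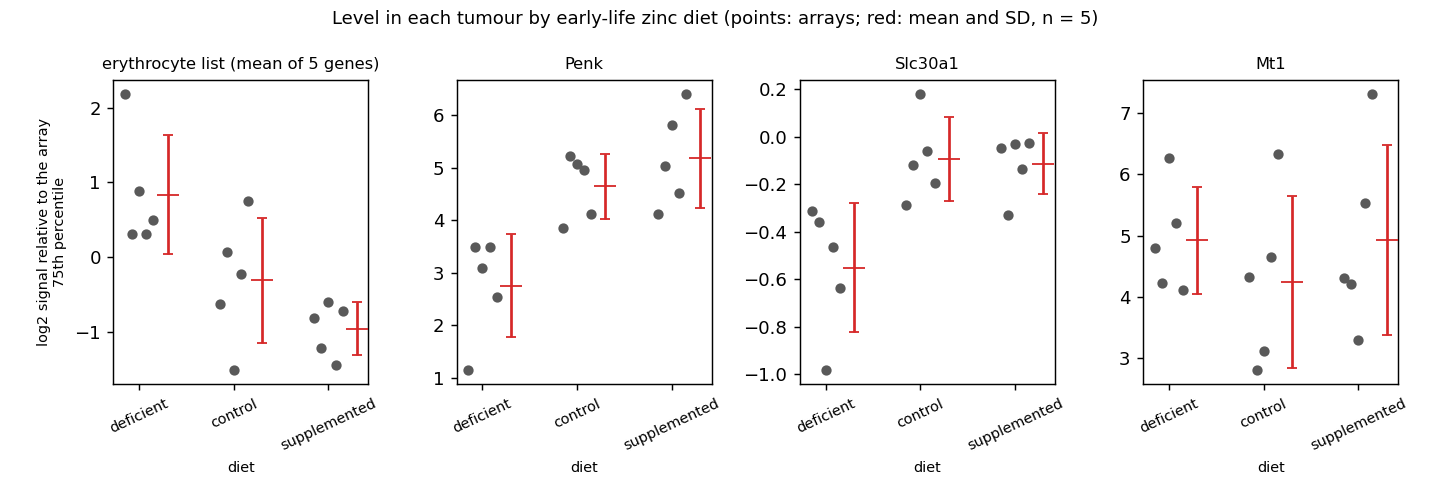
Levels (log2 signal relative to the 75th percentile of the array) of the erythrocyte list, Penk, Slc30a1 and Mt1 in each tumour by diet; points are arrays, and red bars are the mean and SD of 5 tumours. The mean of the erythrocyte list lies at or above 0.31 in the deficient tumours and at or below -0.60 in the supplemented ones, while Mt1 overlaps between the 3 diets.

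Penk was higher in supplemented than in deficient tumours by 2.42 log2 units (5.18 ± 0.94 against 2.75 ± 0.98), and its highest deficient tumour (3.50) lay below the lowest tumour of the other diets (3.85). Within the 4 slides Penk differed by 1.23 to 3.86, and by 2.37 with slide as a block. Other genes higher in supplemented tumours were Mogat1 (1.86, an acyltransferase of triglyceride synthesis), Nrcam (1.73, a neuronal adhesion molecule), Twsg1 (0.84, a modulator of BMP signalling) and Dlat (0.65, a subunit of pyruvate dehydrogenase). Besides Alas2 and Ahsp (-1.59), those lower were Capns2 (-3.59, a small calpain subunit), Gch1 (-1.48, the first enzyme of tetrahydrobiopterin synthesis) and Taf5 (-0.80). Gch1 and Taf5 were well above background in 3 deficient tumours and 1 supplemented tumour each, Ahsp in 4 and 1, Nrcam in 3 and 5, and Capns2 in 5 and 4. Limma called 0 of 21011 probes (lowest adjusted p = 0.615). At an unadjusted p under 0.05 there were 1482 probes, where 1051 are due by chance, and 14 of 100 splits of the tumours reached that count. Without supplemented replicate 1, which had the highest Capns2 level of its diet (3.27), that gene passed with a log2 difference of -4.46 (adjusted p = 0.0263 in limma). This was the lowest adjusted p over the alternatives of Capns2, which reached 0.985.

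Among the remaining lists for this contrast, 18 of 23 heat shock genes were higher, with a median of 0.24, or 0.13 without supplemented replicate 4 (with all arrays, adjusted p = 0.897 with an estimated correlation and 0.0263 with a preset one). Camera with estimated correlations called 0 of 29 lists (1 at an unadjusted p under 0.05), camera with a preset correlation called erythrocytes and heat shock, and fry called erythrocytes. The lists other than erythrocytes had adjusted p from 0.897 to 0.956 with estimated correlations. Adjusted over the list alone, 1 member each passed in the growth factor and heat shock lists, and 0 over all probes. Here too the number of lists was not accounted for.

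**Figure D2:**
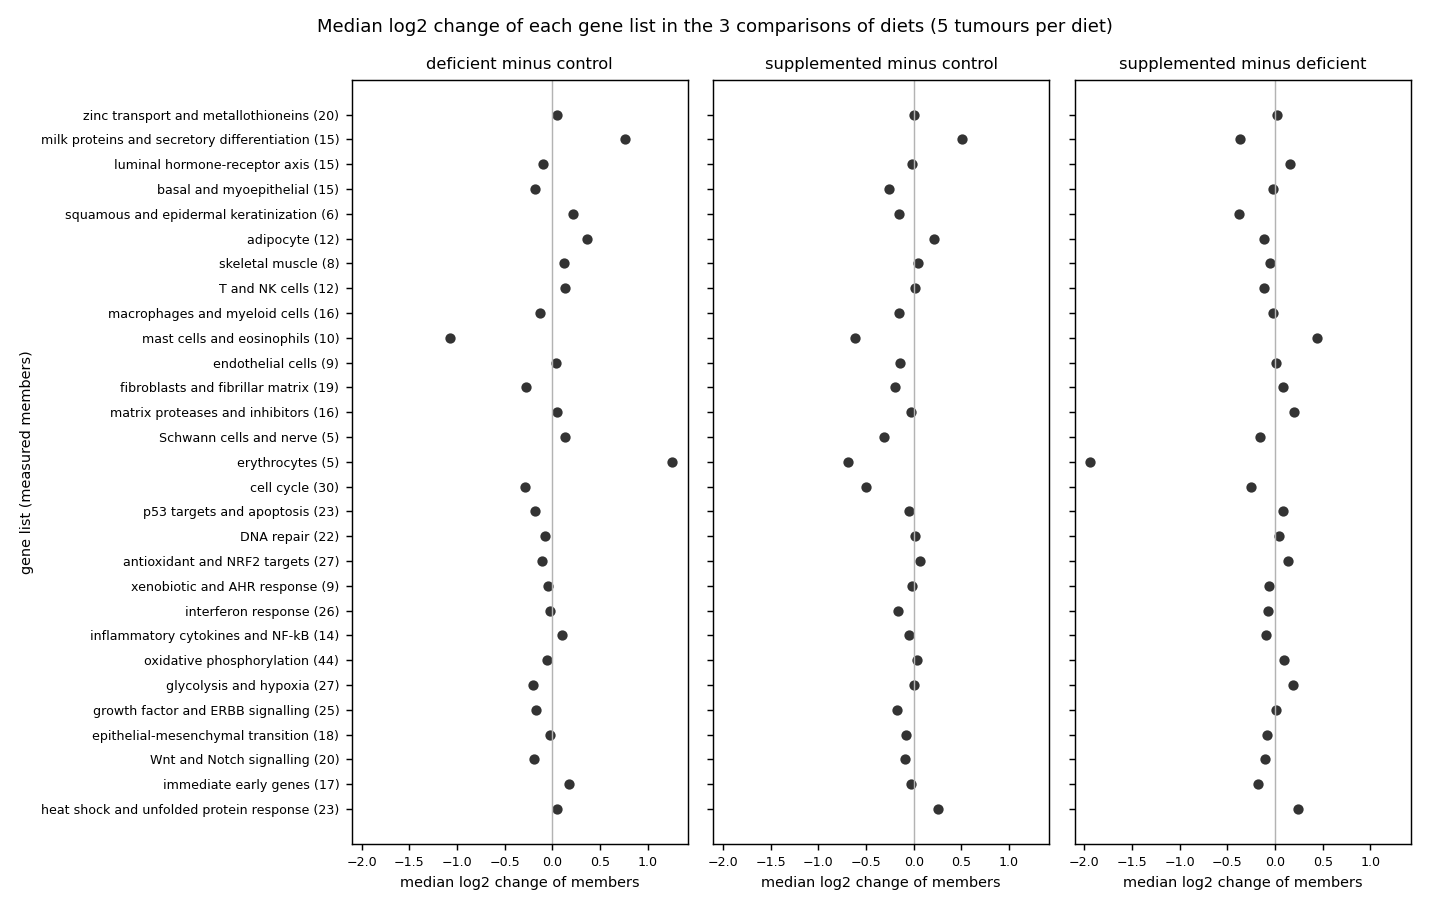
Median log2 change of the measured members of each of the 29 gene lists (vertical axis, members in brackets) in the 3 comparisons of diets (panels); the vertical line marks 0. The erythrocyte list has the highest median for deficient minus control (1.26) and the lowest for supplemented minus deficient (-1.94).

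Zinc transporters and metallothioneins, several of which respond to cell zinc, were tested as a list because zinc was the dietary variable. Slc30a1, the zinc exporter ZnT1, had a level of -0.55 ± 0.27 in deficient tumours, -0.09 ± 0.18 in controls and -0.11 ± 0.13 in supplemented tumours (SD, n = 5 each). Its log2 differences were -0.46 for deficient minus control and 0.44 for supplemented minus deficient, with adjusted p of 0.215 and 0.196 over the list alone. With normexp they were -0.09 and 0.15, and with the deposited values -0.10 and 0.16. Slc39a6, the zinc importer ZIP6, differed by 0.57 between supplemented and deficient tumours (adjusted p = 0.196 over the list alone). The metallothionein gene Mt1 stood at 4.92 ± 0.87 in deficient tumours, 4.24 ± 1.40 in controls and 4.93 ± 1.55 in supplemented tumours, and Mt2A at 4.07 ± 1.09, 3.34 ± 1.11 and 3.90 ± 1.28. The difference of Mt1 between deficient and control tumours was 0.68, and -0.03 with adipocyte, muscle and B cell levels as covariates. Leaving out single arrays gave 0.32 (without control replicate 2) to 1.20 (without control replicate 5), and the difference of 0.69 between supplemented and control tumours ran from 0.09 (without supplemented replicate 5) to 1.21 (without control replicate 5), was also larger without supplemented replicate 3, and was 1.14 with slide as a fixed block. Of the 20 zinc genes measured, 0 passed in any comparison, over the list alone or over all probes, by limma; 1, 0 and 2 had an unadjusted p under 0.05 in deficient minus control, supplemented minus control and supplemented minus deficient. The list as a whole had median log2 differences of 0.05 and 0.00 against control in deficient and supplemented tumours, with adjusted p of 0.955 and 0.916; without control replicate 3 the first was -0.02, and without control replicate 1 the second was -0.07.

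For receptor status, the progesterone receptor gene Pgr stood at 0.00 ± 0.54 in deficient, 0.49 ± 0.31 in control and 0.76 ± 0.42 in supplemented tumours, and Erbb2 at 0.95 ± 0.40, 1.45 ± 0.54 and 1.63 ± 0.25. The log2 differences between supplemented and deficient tumours, 0.76 for Pgr and 0.68 for Erbb2, had adjusted p of 0.665 and 0.678, and were 0.40 and 0.44 with normexp. The 1 named probe of Esr1 was well above background on 2 of 15 arrays and was not tested, and no probe was named Mki67 here. A single dim probe does not show that the tumours lacked the receptor, and RNA levels do not give receptor status.

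The changes of the 2 diets against control had a correlation of 0.33 across 8369 genes, which are not independent replicates. Both share the 5 control tumours, and groups without any effect gave 0.48 on average over 100 simulations (95% of them between 0.13 and 0.76). Spearman's correlation was 0.29. The covariance was 0.0280 against 0.0523 in the simulations, a difference of -0.0243. It lay inside the range of 0.0127 to 0.0920 that held 95% of the simulated values. With the controls split between the comparisons, the correlation was -0.12 on average over the 10 splits, from -0.28 to 0.01. These splits reuse the same tumours and were not simulated without an effect, so their sign does not show opposite changes.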

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

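Tests on array brightness, slide, the floor of dim arrays, nerve tissue and array quality were chosen only after the result was seen. A tumour lay far from the others of its diet in 13 of 225 groups of 5 values over 29 lists, 45 genes and array similarity; chance gives about 1 in 20. In lists, the adipocyte level was 1.47 in supplemented replicate 5, the T and NK cell level 1.13 in deficient replicate 3, the mast cell level -1.78 and the epithelial-mesenchymal transition level 0.61 in supplemented replicate 4, the endothelial level -0.56 in control replicate 2 and the DNA repair level 1.12 in deficient replicate 5. In genes, Ckb was 2.89 in control replicate 1, Nipa2 -2.28 in control replicate 2, F11r 0.88 in control replicate 5 and Nptx1 -1.38 in supplemented replicate 1. Deficient replicate 3 stood apart in Cxcl1 (3.54), Fmod (2.83) and Car15 (-4.14).

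Deficient replicate 3 was the array least like the rest, with a mean correlation of 0.930 with the other arrays against 0.936 for the next lowest. Poor hybridization is argued against by its 19256 spots above background and its spike-in fit of 0.986, both inside the range of the other 14 arrays. Whether more immune cells account for it stays open: taking out the slopes over T cell and macrophage levels left 0.932 against 0.940 for the lowest other array. The slopes were fitted on the other 14 arrays, and that fit can itself raise the similarity of those arrays. The comparison therefore cannot decide. Beyond immune cells no biological explanation was tested, since the design gives none for 1 tumour.

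Erythrocyte transcripts were higher in deficient than in supplemented tumours. Array brightness is argued against, since the median log2 difference was still -1.61 with brightness as a covariate (adjusted p = 0.111, against 0.122 before and 1.86e-09 to 0.672 over the alternatives). The raised floor of dim arrays is argued against by Hbb-b1, far above that floor, at -2.09. Slide is argued against by the median, which was no smaller in size with slide as a block. The differences of -3.01 to -1.21 within the 4 slides add nothing by their sign. They had to lie below 0, because the list mean of every deficient tumour lay above that of every supplemented one. More blood left in deficient tumours may account for it and stays open: 9 of 27 further erythroid genes were measured, with a median of -0.0614, 6 lower (exact two-sided sign test p = 0.508) and 0 at an unadjusted p under 0.05 in limma, too few to decide. Early zinc itself also stays open, and chance is not excluded after correction over the lists.

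Penk was lower in deficient tumours. It was so in each of the 4 slides, which had to be, since every deficient tumour lay below every other tumour. Brightness is argued against, as the difference between supplemented and deficient tumours was 2.40 with it as a covariate (95% interval from 1.30 to 3.50; adjusted p = 0.713, against 0.615 before and 0.30 to 0.985 over the alternatives). More nerve tissue in supplemented tumours is argued against by the Schwann cell and nerve list, whose median was -0.16 in that comparison. Leaving out single arrays gave -0.28 (without deficient replicate 2) to -0.03 (without deficient replicate 1). Other differences in tissue make-up, early zinc deficiency and chance all stay open, and the difference does not pass correction over all probes.

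Any split gives at least 0, so for the counts of 0 the splits decide nothing about chance. Of 100 splits of the tumours, 100 gave at least the 0 probes found for deficient minus control (highest other 151), supplemented minus control (1), supplemented minus deficient (3), the F test (7) and the trend (9), at least the 0 lists (0, 1 and 1 in the same order of comparisons) and at least the 0 zinc genes (3). Chance could not be excluded for the counts at an unadjusted p under 0.05: 73 of 100 splits reached the 822 probes of deficient minus control (highest other 3888), 80 of 100 the 415 of supplemented minus control (1824) and 14 of 100 the 1482 of supplemented minus deficient (2433). The splits with 3888 and with 151 probes put the 4 dimmest arrays of those diets (deficient replicates 1 and 4, control replicates 2 and 5) on one side, which points to a structure by array brightness in that comparison. The highest counts of supplemented minus deficient did not go with it: the split with 2433 probes differed in brightness by 0.301 (log2 of the 75th percentile) between its sides, and the one with the widest difference, 0.855, had 1127 probes.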

How the results depend on the processing

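The brightness covariate and the fit without the 3 dimmest arrays (deficient replicates 1 and 4, control replicate 2) were chosen after seeing the data. Counts of probes were 0 as reported and stayed 0 under every block, scaling, filter, covariate and threshold tried, these 2 included, apart from the following, whose cause was not tested. With only the 2 diets in the fit, 1 unnamed probe passed for deficient minus control; with array weights, 1 unnamed probe passed for supplemented minus deficient and in the F test. Leaving out each array gave 0 to 1 probes for supplemented minus deficient and for the trend, where Capns2 passed without supplemented replicate 1, and 0 for the others. An unadjusted p under 0.05 with a fold of at least 1.5 gave 443 probes for deficient minus control, 235 for supplemented minus control, 809 for supplemented minus deficient, 609 for probes differing between the 3 diets and 849 for probes with a trend over dietary zinc. Normexp on mean spot signals was not run. With probes above background on all 15 arrays, the erythrocyte list (under 5 members left) and the dim named genes gave no value.

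Lists called rose from 0 to 3, 5 and 2 for deficient minus control, supplemented minus control and supplemented minus deficient with a preset correlation, which takes the genes of a list as nearly independent, and to 1 for supplemented minus deficient with fry. All other settings left 0 lists and 0 zinc genes. Of 1989 values of the named genes and of 6 list medians (erythrocytes in 2 comparisons, milk proteins, p53 targets, heat shock, cell cycle) 1 changed sign: Mt1 in deficient minus control was -0.0315 with adipocyte, muscle and B cell levels as covariates, its cause not tested. The other lists were followed only over single arrays left out, where several medians changed sign, among them zinc genes and mast cells (supplemented minus control -0.61, and 0.07 without supplemented replicate 4; supplemented minus deficient 0.44, and -0.27 without deficient replicate 3). The erythrocyte median for supplemented minus deficient kept its sign and ran from -2.11 (without 1 array) to -0.68 (no filter on dim probes, which adds dim members to the list). Its adjusted p lay between 1.86e-09 and 0.672. Normexp, which adds an offset, shrank 33 of 51 differences of named genes by over 1.5 times, and the deposited values 30, none with a change of sign. With normexp the differences in supplemented minus deficient were, for example, -0.78 for Alas2, -0.22 for Gch1 and -0.18 for Taf5. In supplemented minus control they were -0.15 for Phykpl, -0.16 for Guca2a, -0.20 for Pou6f1 and -0.14 for Fam83d. In deficient minus control they were 0.10 for Tgfb2, -0.19 for Nipa2 and 0.43 for Or5b123b. Alas2 and Fam83d were not well above background in any supplemented tumour, so their values here rest on background in that diet.

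With the replicate number as a block, 0 probes, 0 lists and 0 zinc genes passed. The labels do not say that the number pairs the samples, and the levels gave no clear sign of it. Same-numbered tumours had correlations of deviations between -0.28 and 0.22, over 0.1 in 6 of 15 pairs. Of the 15 tumours, 4 correlated best with their own number. Weak correlations cannot exclude a pairing. With slide as a fixed block the erythrocyte median was -2.10 (adjusted p = 0.168), and within the 4 slides the list mean differed by -3.01 to -1.21. Low signal limits dim genes most, since the floor of the dim arrays lies higher relative to their 75th percentile.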

Other observations

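The genes described here and the relations with array brightness were chosen after the values were seen. Levels of cell type markers differed widely between tumours. Skeletal muscle genes reached a mean level of 0.76 in deficient replicate 2 and 0.40 in supplemented replicate 4, against -0.32 or less in the other 13. Adipocyte genes reached 1.90 in deficient replicate 1 and 1.47 in supplemented replicate 5. T and NK cell genes were highest in supplemented replicate 5 (1.31), deficient replicate 3 (1.13) and control replicate 5 (0.59), and the macrophage list was also highest in those tumours (2.44, 2.74 and 2.79). Mast cell genes were lowest in deficient replicate 3 (-1.76) and supplemented replicate 4 (-1.78), and Mcpt1 reached 3.42 but was well above background on 12 of 15 arrays. Cell cycle genes ran from -1.37 in deficient replicate 3 to 0.87 in control replicate 3.

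Among single genes, the imprinted gene Igf2 spanned 6.90 log2 units and the complement gene C3 spanned 6.43, both well above background on 15 of 15 arrays, with 10.4% and 0.768% of the variance going with diet. H19, imprinted beside Igf2, and the urothelial plaque gene Upk3a reached 5.79 and 6.33 and were well above background on 14 and 13 arrays. The median gene had 10.9% of its variance with diet, and 10.9% is what 3 groups of 5 give with no effect.

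Array brightness followed the main axes of the data. The 75th percentile correlated with the first principal component over the 15 arrays (Pearson r = 0.71, permutation p = 0.00306, adjusted 0.00918; Spearman rho = 0.50, permutation p = 0.0614, adjusted 0.0921), with r = 0.48 without the 2 arrays farthest from the median, and with the second (r = -0.61, permutation p = 0.0152, adjusted 0.0228; rho = -0.80, permutation p = 0.00054, adjusted 0.00162; r = -0.57 without those 2), out of 3 components tested. In a fit with brightness alone, 1451 of 21011 probes went with brightness at an adjusted p under 0.05 in limma. Brightness is the same 75th percentile that was subtracted from every level, so part of that count can be built in. It is not a like test for the 0 probes of diet. The mean 75th percentile was 6.58 ± 0.85 in deficient, 6.89 ± 0.72 in control and 6.91 ± 0.26 in supplemented arrays (log2, SD, n = 5 each).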
